A study of Homo sapiens with 42 samples.

How the data were processed

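RNA was measured by sequencing in 42 libraries from MCF7 and T47D, established human breast cancer cell lines that carry hormone receptors. The libraries fell into 13 groups: 11 drug-resistant lines with 3 libraries each, MCF7 parental cells with 6 and T47D parental cells with 3. Palbociclib and abemaciclib are inhibitors of the cell cycle kinases CDK4 and CDK6. Per the labels, the dose of palbociclib was raised from 1.2 to 4.8 µM over 6 months and that of abemaciclib from 0.5 to 1.5 µM over 7 months. Each line was kept at its own dose, but experiments were run without drug unless stated otherwise. The titles call the 3 libraries of a line biological replicates but do not say whether they come from separate cultures.

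The deposited files hold raw counts of reads per gene symbol, 1 file per library. The authors' processing notes name FastQC 0.11.8, TopHat2 2.1.1 and HTSeq 0.11.0 on GRCh38. The gene annotation and the strand setting are not given in the sources used here. Each file lists 57133 gene symbols, all of which were matched in GENCODE release 29, and 5 HTSeq counters of reads that were given to no gene. These counters were left out of all counts per gene and used only to describe the libraries. Reads of the no-feature counter are called reads outside genes below. Total counts in genes ranged from 13009589 to 26752181 per library. At this depth a gene with 0 counts in a group was given a floor of 3 counts over that group, which covers counting error only.

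Changes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit, TMM factors, genes kept by filterByExpr on the groups). One fit held all 27 MCF7 libraries and 8 groups (18059 genes, common dispersion 0.319, 19 residual degrees of freedom). One held all 15 T47D libraries and 5 groups (18245 genes, dispersion 0.0511, 10 degrees of freedom). A fit of all 42 libraries (20243 genes, dispersion 0.232, 29 degrees of freedom) tested whether the change from parental to palbociclib-resistant lines differed between the cell lines. A resistant arm was the mean of its dose lines' coefficients, so that each line had equal weight. Dose trends were linear contrasts over the lines of an arm, in log2 per µM, with the parental cells left out. All tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the fit. Standard errors of log2 fold changes were taken as the size of the change divided by the square root of the F statistic and are approximate. Levels are in CPM (counts scaled by library total and TMM factor), as mean ± SD over libraries. Folds were computed from the fitted log2 change. For genes with 0 counts in a group the fold was instead a bound against the floor, and for 1 to 3 counts a ratio with its counting interval.

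The 31 gene lists (25 pathways, 3 signs of library quality and 3 other cell types) were fixed before the data were examined. They were CDK4/6-RB axis, DNA replication, G2/M and mitosis, homologous recombination and Fanconi repair, oestrogen response, luminal identity, mesenchymal and matrix, basal and stem-like, type I interferon, MHC class I, IL6-JAK-STAT3, NF-kB and cytokines, oxidative phosphorylation, mitochondrially encoded, glycolysis and hypoxia, cholesterol synthesis, fatty acid synthesis, lysosome, ABC transporters, aryl hydrocarbon and NRF2 targets, growth factor receptors, ERK output, unfolded protein and ATF4 response, p53 targets, Hippo-YAP and TGF-beta output, replication-dependent histones, ribosomal proteins, immediate early genes, and fibroblast, leukocyte and endothelial markers. Lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. The same test with an estimated correlation and limma's fry test stood beside it. Some genes stood in more than 1 list. Matching used the release 29 gene models (rtracklayer 1.62.0, Biostrings 2.70.1), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

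Named genes followed a rule fixed before the data were examined. It took, per comparison, the 8 largest increases and 8 largest decreases among called protein-coding genes with a mean of at least 5 CPM in which every library of one side lay above every library of the other. It added 25 fixed genes of the cell cycle, oestrogen receptor, growth factor receptors and drug transport, up to 4 members of each called list in its direction and up to 2 called members against it. For the difference between cell lines it took the 5 largest in each direction among genes that changed in opposite directions, and for dose trends the 4 largest slopes each way among genes whose group means were ordered by dose. Of the 301 genes under the rule, 196 overlap another annotated gene, where counts are uncertain because the strand setting is not given. None had most of its 50-base stretches in another gene. Sex-linked marker genes were left out of the named genes.

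The fits were tested on simulated data with 200 changed genes. Far fewer genes changed there than were called in the data, so the shares below need not describe the data. For MCF7 palbociclib lines 65.5% of 4-fold changes and 7.0% of 2-fold changes were recovered, with 4 false calls among 17083 genes. For MCF7 abemaciclib lines the shares were 69.0% and 12.3% (3 false calls), for T47D palbociclib lines 78.9% and 55.2% (2 false calls), for palbociclib against abemaciclib 70.7% and 3.5% (3 false calls), and for the difference between cell lines 39.2% and 1.5% (1 false call).

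Alternatives fixed before the data were examined were RLE and upper-quartile factors, no count filter, a stricter one (over 1 CPM in at least 3 libraries), DESeq2 1.42.0, at least a 2-fold change, blocks by the replicate number in the titles and by the set number in the library names, dose lines pooled as 1 group, fits of only the groups compared, parental replicates matched to each arm by library name (1 to 3 for palbociclib, 4 to 6 for abemaciclib), highest dose lines only, log2 dose, and each library left out in turn. Chosen after seeing the data were a fit with the share of reads outside genes as a covariate, one without the 4 MCF7 palbociclib libraries of set 1, and the gene lists along the dose. Overlaps of called genes were set beside the count for independent arms and, for arms with shared controls, beside 20 simulations of unchanged groups and controls split between the arms. No gene or library was left out of the comparisons for its values.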

Results

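RNA levels were measured by sequencing in MCF7 and T47D breast cancer cells made resistant to palbociclib or abemaciclib and in their parental cells. MCF7 gave 4 palbociclib-resistant lines (1.2, 2.4, 3.6 and 4.8 µM), 3 abemaciclib-resistant lines (0.5, 1.0 and 1.5 µM) and parental cells, and T47D gave 4 palbociclib-resistant lines at the same doses and parental cells. Each resistant line had 3 libraries, MCF7 parental cells had 6 and T47D parental cells had 3. Counts in genes summed to between 13009589 and 26752181 per library. The titles call the replicates biological but do not say that they are separate cultures, so the p-values measure the spread between these libraries. Intervals and floors cover counting error only, and gene positions are on GRCh38. Levels are mean ± SD over the libraries of a group, and changes are log2 fold changes ± SE.

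The libraries differed in the share of reads that HTSeq gave to no annotated feature, here called reads outside genes. Depending on the counting settings, these can include intronic or antisense reads within genes. That share was 2.79 to 9.54% in MCF7 parental cells, 1.36 to 13.5% in the MCF7 palbociclib lines and 1.63 to 2.9% in the abemaciclib lines, against 10.6 to 12% in T47D parental cells and 9.94 to 12.8% in the libraries labelled T47D palbociclib-resistant. The median number of genes detected was 21950 in MCF7 parental cells, 19820 in the palbociclib lines and 16820 in the abemaciclib lines. The 4 libraries of set 1 among the MCF7 palbociclib lines (replicate 1 of each, by the number in the library names) had shares of 1.36 to 2.14%. They stood apart on the second principal component of the MCF7 libraries, at -162.8 to -88.7 against -76.9 to 56.6 for the other 8. Across the 27 MCF7 libraries that component followed the share (Pearson r = 0.783, permutation p = 2e-05, and 0.837 without the 2 farthest libraries; Spearman rho = 0.863, permutation p = 1e-05, the smallest that the permutations can give), and r was 0.878 within the palbociclib lines. The 50 most abundant genes took a median of 21.5, 24.2 and 29.3% of the counts in these groups. The median log2 change of all tested genes was -0.48 in the abemaciclib lines against parental cells with TMM factors and -0.37 with RLE factors, and the changes below are those fitted with TMM factors, with this median not taken out.

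**Figure D1:**
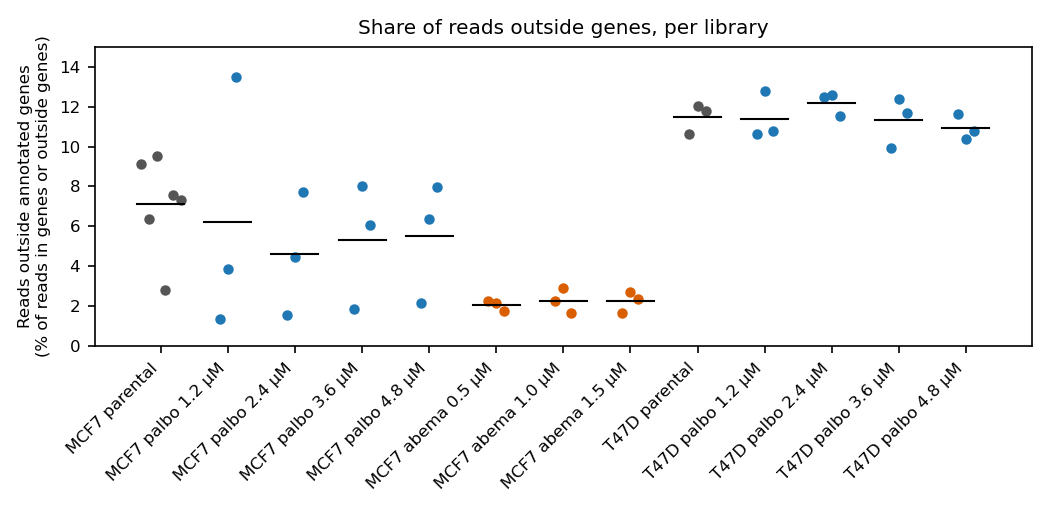
Each point is 1 library and each bar the mean of a group. The vertical axis gives reads that HTSeq gave to no annotated feature, as a percent of those reads and reads in genes. The 9 abemaciclib libraries lay between 1.63 and 2.9%, below 5 of the 6 MCF7 parental libraries.

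The first comparison asked how MCF7 lines resistant to palbociclib differ from parental MCF7 cells. Genes of luminal epithelial cells fell and genes of mesenchymal cells and their matrix rose. Across genes, the palbociclib line means had a Spearman rho of 0.852 to 0.861 with MCF7 parental cells, against 0.868 between MCF7 and T47D parental cells. With the lines labelled T47D palbociclib-resistant rho was 0.907 to 0.935. Whether these changes arose in MCF7 cells or reflect other cells in these cultures stays open. FOXA1, a transcription factor that opens chromatin for the oestrogen receptor (chromosome 14, 37589984 to 37596059), fell 338-fold, from 228 ± 30.2 CPM (n = 6) to 0.753 ± 0.375 CPM (n = 12; -8.40 ± 0.20, adjusted p = 5.85e-21). CDH1, which encodes E-cadherin, fell 115-fold, from 660 ± 52.2 to 6.53 ± 3.76 CPM (adjusted p = 9.89e-17). ELF5, a luminal transcription factor (chromosome 11, 34478793 to 34513805), went from 70.7 ± 18.8 CPM to 0 counts, at least 5677-fold lower. COL6A1, a collagen chain (chromosome 21, 45981737 to 46005050), rose from 2.33 ± 0.553 to 2541 ± 1184 CPM (9.99 ± 0.46, adjusted p = 4.77e-15), and SERPINE1, an inhibitor of plasminogen activators, from 1.37 ± 0.663 to 1770 ± 742 CPM (10.26 ± 0.47, adjusted p = 4.77e-15).

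In the same comparison the other largest falls were those of RPRM, CLEC3A, CYP4Z1, SPDEF, ADAMTS19, GRHL2 and ALDH3B2. SPDEF and GRHL2, both transcription factors of epithelial cells, went from 236 ± 115 to 0.0545 CPM and from 118 ± 26.4 to 0.0132 CPM. ADAMTS19 had 1 count in the resistant lines, a ratio of 9383 with a counting interval of 1684 to 370600. RPRM and CLEC3A had 0 counts there and were at least 1710-fold and 1704-fold lower. The other largest increases were those of DPYSL5, CCBE1, FXYD5, IL7R, P3H2, AXL, IGF2BP2 and FBXO2. AXL, a receptor tyrosine kinase, rose from 0.225 ± 0.149 to 377 ± 295 CPM (adjusted p = 1.26e-10). DPYSL5 and CCBE1 had 0 counts in parental cells and were at least 1479-fold and 1430-fold higher, while IL7R had 2 counts, a ratio of 3669 with an interval of 1016 to 30290. The groups did not overlap in any of the genes named so far, which the naming rule required for the 8 largest increases and 8 largest decreases.

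The oestrogen receptor gene ESR1 (chromosome 6, 151656691 to 152129619) fell 10.8-fold in the MCF7 palbociclib lines, from 87.6 ± 14.9 to 8.24 ± 4.23 CPM (-3.43 ± 0.34, adjusted p = 6.15e-09). Its target TFF1 fell from 90.7 ± 72.4 to 0.12 CPM and the survival gene BCL2 from 10.6 to 0.18 CPM. The target GREB1 fell from 24.8 ± 23.1 to 4.65 CPM, with groups that overlapped. Of the growth factor receptors, EGFR rose 5.7-fold, from 13.8 ± 3.99 to 85.6 ± 55.6 CPM (2.51 ± 0.35, adjusted p = 1.74e-06), and ERBB2 fell from 183 to 47.6 CPM (-1.99 ± 0.26, adjusted p = 4.74e-07). ABCG2, a drug efflux pump, fell from 22.6 to 1.27 CPM, and the pump gene ABCB1 was too low to be tested in any fit.

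Among genes of the cell cycle in these lines, CCNE1, which encodes the CDK2 partner cyclin E1, rose 2.7-fold from 11.2 ± 3.75 to 30.7 ± 11.2 CPM (1.43 ± 0.28, adjusted p = 0.000132). CDK6, a target of both drugs, fell 6.72-fold from 15.4 to 2.69 CPM (-2.75 ± 0.34, adjusted p = 2.71e-07). The CDK inhibitor CDKN1B fell from 57.5 to 16.02 CPM (adjusted p = 3.81e-07). RB1, which encodes the protein that CDK4 and CDK6 phosphorylate, went from 20.1 to 7.22 ± 9.24 CPM (-1.59 ± 0.63, adjusted p = 0.0422), a call lost under 4 of 13 alternatives and without any 1 of 10 libraries. The calls of CDK4 (1.15 ± 0.39, adjusted p = 0.0192), CCND1 (0.61 ± 0.21, adjusted p = 0.0217) and E2F1 (1.17 ± 0.37, adjusted p = 0.0116) were lost under 1, 5 and 4 alternatives. CDK2, CCND3, CCNE2, CDKN1A and the proliferation marker MKI67 were not called, with MKI67 at 207 ± 110 against 285 ± 257 CPM (adjusted p = 0.447).

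Of the luminal list, 27 of 29 members fell and 0 rose, also when adjusted over the list alone (adjusted p of the list = 2.73e-20, and 5.58e-08 with an estimated correlation). Of the mesenchymal and matrix list, 42 of 54 rose and 1 fell, or 43 and 1 adjusted over the list alone (8.53e-23 and 2.34e-06). TGFBI and COL5A1, matrix proteins, rose 128-fold to 699 ± 203 CPM and from 8.12 to 1665 CPM. Hippo-YAP and TGF-beta output genes rose in 26 of 33 members and fell in 2 (27 and 2 adjusted over the list alone; 1.59e-12 and 0.000384). They included PMEPA1 (3.89), the coagulation factor gene F3 (0.603 to 186 CPM) and CYR61 (5.54 to 79.2 CPM), with the TGF-beta antagonist BAMBI falling (-3.56). In the glycolysis and hypoxia list 30 of 39 members rose and 1 fell (31 and 1 adjusted over the list alone; 1.95e-11 and 0.0224). BNIP3 rose 12.9-fold to 213 ± 62.3 CPM and the carbonic anhydrase gene CA9 rose from 0.468 to 156 CPM.

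Inflammatory and signalling lists were called in the MCF7 palbociclib lines as well. Of NF-kB and cytokine genes 22 of 37 rose and 7 fell (24 and 8 adjusted over the list alone; adjusted p = 1.58e-05, and 0.00939 with an estimated correlation), with complement C3 going from 4.70 to 97.6 CPM and the growth factor CSF1 from 2.75 to 49.9 CPM. Of IL6-JAK-STAT3 genes 19 of 32 rose and 1 fell (the same counts adjusted over the list alone; 0.000381 and 0.00611), with the cytokine genes IL11 and LIF rising from 0.762 to 26.3 and from 2.49 to 58.3 CPM. ERK output genes rose in 16 of 31 members and fell in 3 (adjusted p = 0.000132, lost at 0.129 with an estimated correlation). They included the AP-1 gene FOSL1 (1.56 to 251 CPM) and the receptor gene EPHA2 (38.3 to 587 CPM). Basal and stem-like genes rose in 14 of 25 members and fell in 5 (14 and 7 adjusted over the list alone; adjusted p = 0.00874, lost at 0.0703). The adhesion receptor CD44 rose 9.04-fold to 415 ± 120 CPM and the hair keratin KRT81 from 5.34 to 1429 CPM, while SOX2 fell from 33.5 to 0.069 CPM.

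The remaining called lists lost their call with an estimated correlation (adjusted p 0.711 to 0.848). Type I interferon genes rose in 23 of 49 members and fell in 6 (adjusted p = 0.0141, 0.746 estimated), with ISG15 going from 5.73 to 88.3 CPM and OAS3 falling (-2.22). MHC class I genes rose in 9 of 21 and fell in 2 (0.0273), lysosome genes in 17 of 56 and 8 (0.0461), DNA replication genes in 11 of 50 and 1 (0.0426), and ribosomal protein genes in 28 of 78 and 1 (0.000381), while histone genes fell in 10 of 20 and rose in 0 (0.0427). The calls of the MHC class I, ribosomal and histone lists were also lost in the highest dose line (adjusted p = 0.176, 0.859 and 0.509). Without set 1, an alternative chosen after the data were seen, these 3 calls (0.0888 each) and that of the lysosome list (0.25) were lost. With the share of reads outside genes as a covariate, chosen likewise, those of the MHC class I (0.0718), histone (0.0577) and lysosome lists (0.109) were. The call of DNA replication was lost without parental replicate 1 (0.538) or replicate 3 of the 4.8 µM line, and those of the lysosome and histone lists were lost without any 1 of 8 and 5 libraries. Lists not called were CDK4/6-RB (9 rose and 7 fell of 25), G2/M (1 and 0 of 50), homologous recombination (0 and 1 of 28), oestrogen response (11 and 20 of 44), oxidative phosphorylation (15 and 11 of 77), mitochondrially encoded (0 and 0 of 13), cholesterol synthesis (0 and 11 of 24), fatty acid synthesis (7 and 13 of 30), ABC transporters (6 and 6 of 16), aryl hydrocarbon and NRF2 targets (5 and 15 of 34), unfolded protein and ATF4 (5 and 15 of 40), p53 targets (7 and 7 of 34), immediate early genes (8 and 5 of 22), fibroblast markers (0 and 0 of 3) and endothelial markers (2 and 2 of 6). In the growth factor receptor list, also not called, 9 rose and 11 fell of 26, with a median of -0.14 and a mean of 0.08. Median, mean and test also differed in sign for the fibroblast and endothelial markers. Without set 1 the lists of G2/M (up, adjusted p = 0.00654), unfolded protein and ATF4 (down, 0.000819), cholesterol synthesis (down, 0.0256) and aryl hydrocarbon and NRF2 targets (down, 0.0409) were called. Cholesterol synthesis was also called with the covariate (0.0156).

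edgeR called 7942 of 18059 genes between the MCF7 palbociclib lines and parental cells, 3614 higher and 4328 lower. In 2790 called genes all libraries of one side lay above all of the other, which chance gives in 0.0108% of genes.

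**Figure D2:**
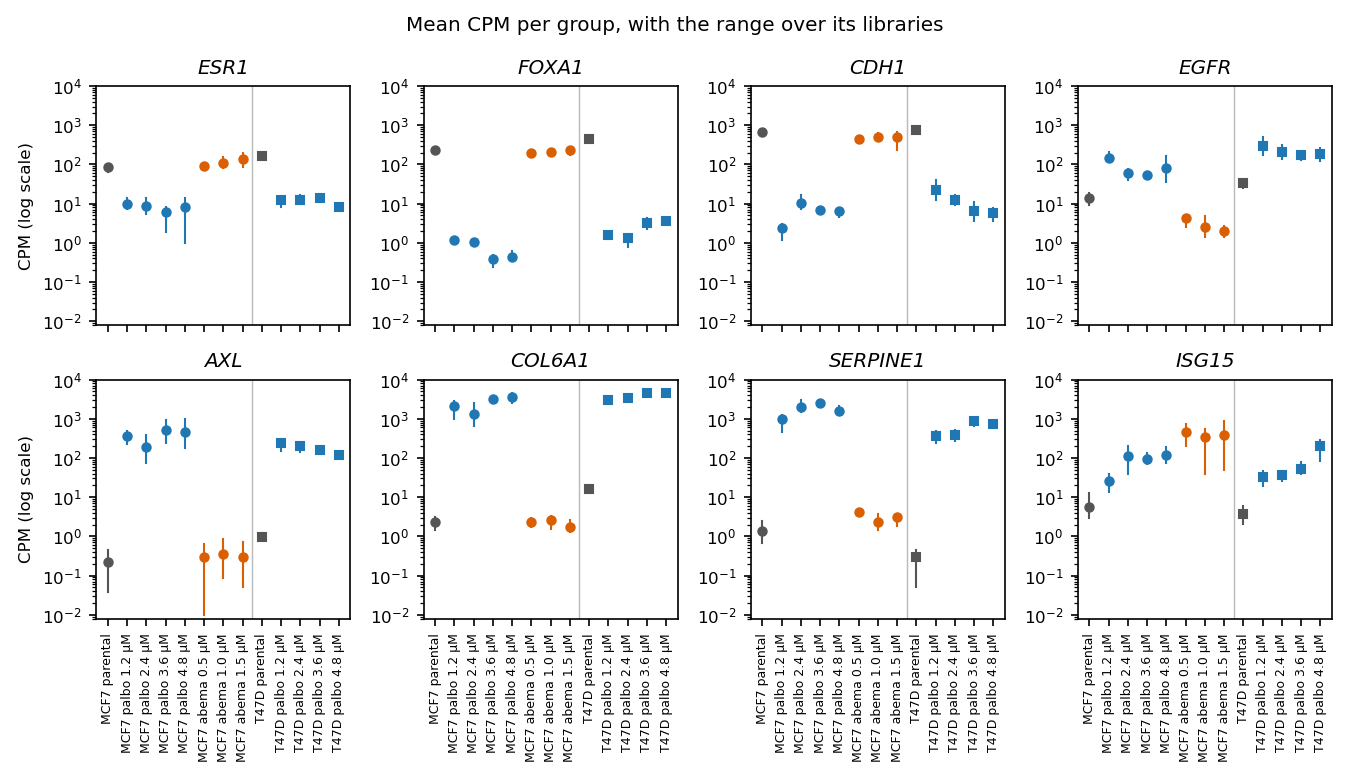
Mean CPM on a log axis for 8 genes in the 13 groups, with bars for the range over the libraries of a group and values under 0.01 drawn at 0.01. ESR1 was at 8.24 CPM in the MCF7 palbociclib lines against 87.6 in parental cells and 112 in the abemaciclib lines, and ISG15 was at 400.3 CPM in the abemaciclib lines against 5.73.

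The second comparison asked the same of the MCF7 lines resistant to abemaciclib. The largest increases were mostly those of interferon-stimulated genes. IFI6 (chromosome 1, 27666061 to 27672218) rose 80.3-fold, from 12.7 ± 3.31 (n = 6) to 1038 ± 677 CPM (n = 9; 6.33 ± 0.68, adjusted p = 1.46e-06), ISG15 69.3-fold from 5.73 ± 3.5 to 400.3 ± 295 CPM (adjusted p = 3.01e-06), and IFI27 291-fold to 77.2 ± 58.2 CPM. OAS2, OASL, IFITM1 and the chemokine gene CCL5 rose between 52.6-fold and 92.4-fold. PCDH10, a cell adhesion protein (chromosome 4, 133149315 to 133208606), rose 532-fold, from 0.135 ± 0.183 to 81.5 ± 40.6 CPM (9.06 ± 0.65, adjusted p = 2.98e-08). The largest falls were those of SLITRK6 (132-fold, 32.1 ± 17.3 to 0.486 CPM), IGFBP5, PLEKHH2, ALDH1L2, N4BP2, SLC7A11, ATM and DMTF1. SLC7A11, the cystine transporter, fell 19.7-fold and the DNA damage kinase ATM 17.6-fold. All 9 abemaciclib libraries lay on one side of all 6 parental libraries in each of these 16 genes, which the rule for naming the largest changes required.

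ESR1 was not called in the abemaciclib lines (112 ± 39.5 against 87.6 ± 14.9 CPM; 0.33 ± 0.37, adjusted p = 0.454), while GREB1 fell 7.26-fold (adjusted p = 3.34e-05) and TFF1 was not called (-0.97, adjusted p = 0.0875). EGFR fell 4.89-fold, from 13.8 to 2.94 ± 1.57 CPM (-2.29 ± 0.33, adjusted p = 2.68e-05). CCNE1 (chromosome 19, 29811898 to 29824308) rose 5.9-fold from 11.2 ± 3.75 to 68.2 ± 23 CPM (2.56 ± 0.30, adjusted p = 4.4e-06) and the cyclin gene CCND3 from 92.4 to 282 CPM (adjusted p = 0.00022). MKI67 fell 5.15-fold, from 285 ± 257 to 55.9 ± 17.8 CPM (adjusted p = 0.000588), in groups that overlapped. Its parental mean rests in part on replicate 2, at 772.6 CPM against 34.6 to 276.1 in the other 5, without which the change was -1.76 and still called. CDKN1B fell by 1.24 on the log2 scale. RB1 went from 20.1 ± 7.37 to 3.15 ± 1.73 CPM (-2.69 ± 0.70, adjusted p = 0.00257). With the share of reads outside genes as a covariate, chosen after the data were seen, the change of RB1 was -0.82 and its call was lost. The same held for CDK4 (1.62 without and 0.57 with the covariate), E2F1 (1.50 and 0.67), CCNE2 (-2.70 and -0.64), ERBB2 (0.97 and 0.31), STAT3 (0.65 and 0.29) and BCL2 (-0.99 and -0.32). CDK6, CDK2, CCND1, CDKN1A, FGFR1 and ABCG2 were not called.

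Of the type I interferon list, 29 of 49 members rose and 0 fell in the abemaciclib lines, also when adjusted over the list alone (adjusted p = 9.72e-13, lost at 0.281 with an estimated correlation). The other 8 list calls in these lines were lost in the same way (0.263 to 0.769). MHC class I genes rose in 15 of 21 members and fell in 2 (16 and 3 adjusted over the list alone; 2.75e-06, 0.281 estimated), with HLA-B going from 4.03 to 34.5 CPM, the immunoproteasome subunit PSMB9 rising 30.9-fold, and the chaperone CANX falling (-1.38). NF-kB and cytokine genes rose in 15 of 37 and fell in 4 (0.000845, 0.263 estimated), with NFKB2 going from 27.6 to 104 CPM and NFKBIZ falling (-2.99). Aryl hydrocarbon and NRF2 targets rose in 16 of 34 and fell in 8 (0.0166, 0.281 estimated). The pentose phosphate enzyme G6PD rose 5.89-fold to 5018 ± 1317 CPM, while the glutathione synthesis gene GCLC fell (-2.00). Lysosome genes rose in 26 of 56 and fell in 12 (27 and 12 adjusted over the list alone; 0.000845, 0.39 estimated), and their regulator TFEB rose 7.17-fold from 11.8 to 84.8 CPM.

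Oxidative phosphorylation genes rose in 48 of 77 members and fell in 7 (51 and 7 adjusted over the list alone; adjusted p = 1.98e-10, 0.281 with an estimated correlation), with SDHC going from 96.6 to 248 CPM. Ribosomal protein genes rose in 55 of 78 and fell in 3 (58 and 3; 1.09e-12, 0.476 estimated), histone genes in 9 of 20 and 0 (7e-05, 0.281 estimated), and mitochondrially encoded genes in 4 of 13 and 0 (2 and 0 adjusted over the list alone; 0.0139, 0.769 estimated). With the share of reads outside genes as a covariate the call of the mitochondrially encoded genes was lost (adjusted p = 0.0523), and the unfolded protein and ATF4 list was called (down, 4.57e-10). Without the covariate, lists not called were the unfolded protein and ATF4 list (1 rose and 20 fell of 40, adjusted p = 0.0616), homologous recombination (2 and 21 of 28, 0.0686), G2/M (5 and 26 of 50) and DNA replication (7 and 19 of 50). The luminal (11 and 9 of 29) and mesenchymal lists (7 and 9 of 54) were not called either, nor were the 15 other lists tested here. The DNA replication list had a median of -0.22 and a mean of -0.38 with a test that pointed up. Median, mean and test also differed in sign for the CDK4/6-RB, mesenchymal, basal, IL6-JAK-STAT3, fatty acid, growth factor receptor, immediate early and endothelial lists.

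The abemaciclib and parental libraries did not overlap in 3895 called genes, where chance would give 0.04% of genes if all libraries were independent. edgeR called 10268 of 18059 genes between the abemaciclib lines and parental cells, 3694 higher and 6574 lower. With the covariate the count was 3561, of which 3242 were called without it, and with only parental replicates 4 to 6, whose library names go with this arm, it was 6183.

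The third comparison set the 12 libraries labelled T47D palbociclib-resistant against 3 of T47D parental cells. Across genes, the 4 line means of those libraries had a Spearman rho of 0.841 to 0.848 with MCF7 parental cells and 0.810 to 0.814 with T47D parental cells, so each direction below is drawn between groups whose labels alone tie them to one cell line. Genes are not independent replicates. The progesterone receptor gene PGR (chromosome 11, 101029624 to 101130524) fell from 686 ± 111 to 0.0195 CPM (-15.00 ± 0.23, adjusted p = 7.75e-17) and GREB1 88.8-fold from 688 ± 147 to 7.75 ± 1.66 CPM (adjusted p = 7.59e-16). ESR1 fell 14.4-fold, from 167 ± 16.4 to 11.8 ± 3.05 CPM (-3.85 ± 0.14, adjusted p = 8.3e-14). FOXA1 fell 196-fold and the luminal keratin KRT19 166-fold, from 3872 ± 258 to 25.2 CPM. CAV1, the main protein of caveolae (chromosome 7, 116524785 to 116561184), rose from 0.233 ± 0.15 to 673 ± 162 CPM (11.44 ± 0.26, adjusted p = 4.91e-16), and the basal keratin KRT6A from 0.485 to 1910 ± 624 CPM.

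Other genes with the largest changes in these libraries were MGP, SLC40A1, SERPINA6, PIP, NCAM2, KRT23 and TMPRSS13, which fell, and COL8A1, RAMP1, ADAMTS9, TSPYL5, SLIT2, PCSK1N, SAA1 and STRA6, which rose. MGP, a matrix protein, went from 882 ± 113 to 0.019 CPM, and TMPRSS13 to 0 counts, at least 6712-fold lower. PIP had 3 counts left, a ratio of 39330 with an interval of 13460 to 190700. COL8A1, a collagen chain, had 0 counts in parental cells and 130 ± 97.8 CPM in the resistant libraries, at least 2461-fold higher, and the acute phase gene SAA1 had 2 counts, a ratio of 7646 with an interval of 2117 to 63140. EGFR rose 6.09-fold to 214 ± 107 CPM (2.61 ± 0.37, adjusted p = 5.84e-06) and ERBB2 fell 5.69-fold. CCNE1 rose 3.77-fold from 10.8 ± 0.939 to 42.4 ± 15.8 CPM (1.92 ± 0.21, adjusted p = 3.27e-07), CDK6 2.11-fold, and CDKN1A, which encodes the CDK inhibitor p21, from 62.1 to 126 CPM.

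CDKN2A, which encodes the CDK4 and CDK6 inhibitor p16, fell 30.5-fold in these libraries, from 49.1 ± 7.12 to 1.60 ± 0.368 CPM (-4.93 ± 0.17, adjusted p = 5.11e-14). RB1 fell 1.92-fold from 84.1 ± 2.81 to 44.0 ± 6.62 CPM (adjusted p = 3.76e-07), CDK2 2.54-fold, CCNE2 from 23.1 to 4.49 CPM and E2F1 from 87.1 to 42.1 CPM. MKI67 (321 against 392 CPM, adjusted p = 0.125), FGFR1, CDKN1B and ABCG2 were not called. CCND1 rose (0.60, adjusted p = 0.00697), a call lost without parental replicate 1. Calls of CDK4, CCND3 and STAT3 (0.50, 0.74 and -0.54) rest on changes under 2-fold.

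The luminal list fell in 29 of 30 members and rose in 0 (adjusted p = 1.33e-14, and 0.00759 with an estimated correlation), and the mesenchymal and matrix list rose in 43 of 55 and fell in 4 (45 and 5 adjusted over the list alone; 5.99e-11 and 0.00759). COL6A1 rose 228-fold to 3828 ± 863 CPM, while MYL9, a myosin light chain, fell from 94.0 to 0.0506 CPM. Calls of the other 12 lists were lost with an estimated correlation (adjusted p 0.128 to 0.969). The oestrogen response list fell in 32 of 46 members and rose in 11 (adjusted p = 0.000317, 0.128 estimated), with the chemokine CXCL12 going from 211 to 1.40 CPM and IGFBP5 from 1544 to 0.737 CPM, against PRSS23, which rose (5.06). NF-kB and cytokine genes rose in 31 of 41 members and fell in 3 (4.29e-07, 0.337 estimated), with C3 going from 6.19 to 791 CPM. IL6-JAK-STAT3 genes rose in 20 of 32 and fell in 4 (0.000683), with LIFR going from 3.08 to 394 CPM. ERK output rose in 22 of 32 and fell in 5 (0.00195), Hippo-YAP and TGF-beta output in 24 of 33 and 8 (0.00135), basal genes in 16 of 24 and 7 (0.0269) and ribosomal protein genes in 54 of 78 and 7 (0.000119).

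p53 targets rose in 20 of 34 members and fell in 5 in the same libraries (adjusted p = 0.00249, 0.489 with an estimated correlation), with the phosphatase PPM1D rising 6.33-fold and TP53I3 falling from 222 to 10.7 CPM, and the call was lost in the highest dose line (0.0501). PPM1D lies in the chromosome 17 block described below. On a scaling of all 42 libraries it stood at 115.9 CPM here, 17.99 in T47D and 202.5 in MCF7 parental cells. DNA replication genes fell in 26 of 50 members and rose in 4 (0.00736, 0.946 estimated) and G2/M genes in 28 of 50 and 5 (0.0434, 0.969 estimated), with TK1 going from 231 to 71.8 CPM and CDK1 from 232 to 46.8 CPM. With the highest dose line alone both calls were lost (DNA replication at adjusted p = 0.0501), and the G2/M call was lost without any 1 of 8 libraries. Cholesterol synthesis genes fell in 16 of 24 and rose in 3 (0.00933, 0.811 estimated), with DHCR24 going from 716 to 248 CPM. Of 4 endothelial markers tested, 4 rose from 0 parental counts (0.012, 0.128 estimated), EMCN to 5.57 and PECAM1 to 5.38 CPM. Their fitted median was 7.98, or 6.08 at the floor, and the call was lost in the highest dose line (0.0619) and without any 1 of 13 libraries. The fibroblast (3 rose and 1 fell of 6) and leukocyte markers (1 and 1 of 3) were not called, nor were the interferon list (24 and 14 of 52, adjusted p = 0.154) and the 14 other lists tested. Median, mean and test differed in sign for the MHC class I, lysosome, aryl hydrocarbon and NRF2, growth factor receptor, unfolded protein and leukocyte lists.

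edgeR called 12209 of 18245 genes here, 6044 higher and 6165 lower, and 7713 with at least a 2-fold change. The groups did not overlap in 9021 called genes, where chance would give 0.44% of genes if all libraries were independent.

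**Figure D3:**
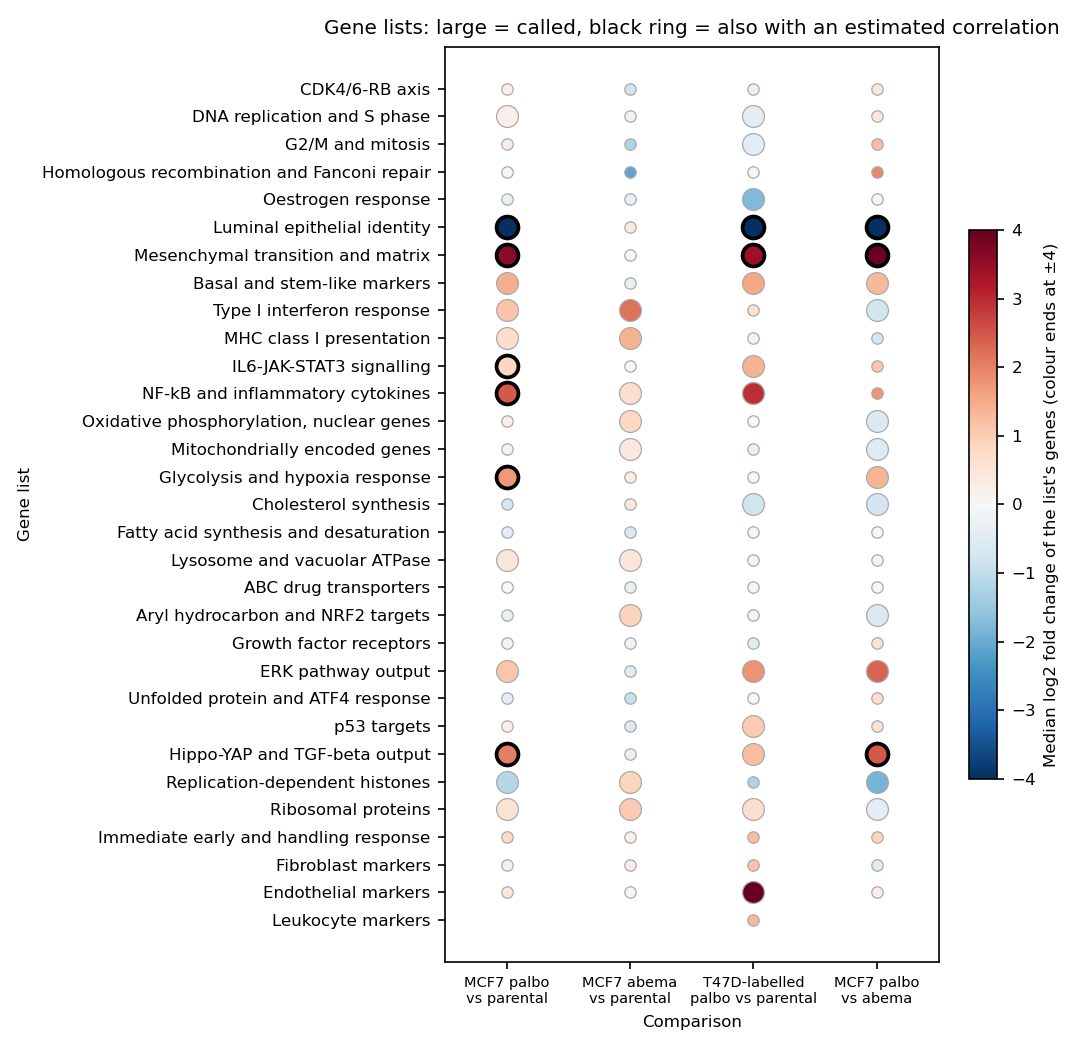
Each point is a gene list in 1 of the 4 comparisons, coloured by the median log2 fold change of its genes (ends at ±4); large points were called, and a black ring marks a call that also held with an estimated correlation. The luminal list had medians of -4.35 and -5.83 in the MCF7 and T47D-labelled palbociclib libraries and 0.33 in the abemaciclib lines.

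The fourth comparison set the 4 MCF7 palbociclib lines against the 3 MCF7 abemaciclib lines, whose doses and months of selection differ, so no dose was matched. Whether the palbociclib lines hold MCF7 cells alone stays open, as in the first comparison. The palbociclib lines were lower in luminal genes and higher in mesenchymal ones. They were also lower in interferon genes, a list call lost with an estimated correlation (adjusted p = 0.589) and in the highest dose lines (0.0623). AZGP1, a secreted glycoprotein of luminal cells (chromosome 7, 99966720 to 99976157), was at 0.119 CPM (n = 12) against 827 ± 294 CPM (n = 9; -12.72 ± 0.50, adjusted p = 2.46e-16). ALDH3B2, SPDEF, CSTA, GRHL2, ELF5, RPRM and PCDH10 were the other largest falls, with ALDH3B2 at 0.024 against 345 ± 100 CPM. The largest increases were IL7R, P3H3, MSLN, CSF3, NTNG1, DPYSL5, CYBA and ZEB1. MSLN, a surface protein, stood at 192 ± 142 against 0.156 CPM. ZEB1, a repressor of CDH1, stood at 15.3 ± 13.9 CPM against 1 count, a ratio of 2225 with an interval of 399.4 to 87900. The DPYSL5 call was lost with arm-matched parental replicates.

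ESR1 was 13.6-fold lower in the palbociclib lines than in the abemaciclib lines (8.24 against 112 ± 39.5 CPM; -3.76 ± 0.33, adjusted p = 3.54e-10), EGFR 27.9-fold higher (85.6 against 2.94 CPM; 4.80 ± 0.34, adjusted p = 6.72e-12) and ERBB2 7.76-fold lower (adjusted p = 1.17e-10). CCNE1 was lower (30.7 against 68.2 CPM; -1.13 ± 0.23, adjusted p = 0.000123) and MKI67 higher (207 against 55.9 CPM; 1.90 ± 0.45, adjusted p = 0.000705). Both calls were lost when each arm was set against its own parental replicates. RB1 (1.10 ± 0.60, adjusted p = 0.108), CDK4 (-0.47 ± 0.33, adjusted p = 0.204) and E2F1 (-0.33 ± 0.31, adjusted p = 0.347) were not called. The CCND1 call (0.43, adjusted p = 0.0452) was lost under 9 of 13 alternatives and reversed in the highest dose lines (-0.33).

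The luminal list was lower in 27 of 29 members and higher in 1 (adjusted p = 3.69e-19, and 7.92e-08 with an estimated correlation), the mesenchymal list higher in 47 of 54 and lower in 2 (47 and 3 adjusted over the list alone; 3.88e-15 and 4.99e-05) and Hippo-YAP and TGF-beta output higher in 29 of 33 and lower in 3 (9.42e-10 and 0.00165). FOXA1 was 311-fold and CDH1 81.4-fold lower, and COL6A1 stood at 2541 against 2.26 CPM. The other 10 calls were lost with an estimated correlation (adjusted p 0.143 to 0.835). ERK output was higher in 25 of 31 and lower in 3 (3.05e-05), with ETV5 at 71.7 against 0.787 CPM, and glycolysis and hypoxia genes in 27 of 39 and 1 (1.11e-05), with NDRG1 at 3772 against 16.1 CPM. Basal genes were higher in 14 of 25 and lower in 5 (0.0426, lost without set 1). Interferon genes were lower in 22 of 49 and higher in 2 (0.000472, 0.589 estimated), with OAS3 35.9-fold lower and HERC5 higher (3.20). In the highest dose lines the interferon call was lost (adjusted p = 0.0623). Histone genes were lower in 20 of 20 (8.07e-07), oxidative phosphorylation genes in 38 of 77 and higher in 4 (7.27e-05), ribosomal protein genes in 36 and 10 of 78 (0.00756), cholesterol synthesis genes in 13 and 1 of 24 (0.00132), aryl hydrocarbon and NRF2 targets in 16 and 8 of 34 (0.00486) and mitochondrially encoded genes in 8 and 0 of 13 (0.0136). The calls of the ribosomal and mitochondrially encoded lists were lost with the share of reads outside genes as a covariate, and 17 other lists were not called. Without set 1, G2/M (up, adjusted p = 0.00905), homologous recombination (up, 0.00905), lysosome (down, 0.0482) and MHC class I genes (down, 0.0487) were called, in the highest dose lines NF-kB and cytokine genes (0.0352) and with the covariate IL6-JAK-STAT3 genes (0.0497). Among the 17, median, mean and test differed in sign for the oestrogen response (16 higher and 16 lower of 44), fatty acid, lysosome, ABC transporter and endothelial lists.

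The MCF7 palbociclib and abemaciclib libraries did not overlap in 2686 called genes (chance, 0.00068% if all libraries were independent). edgeR called 11980 of 18059 genes between the drugs, 7074 higher and 4906 lower in the palbociclib lines. With arm-matched parental replicates the count was 3992 and in the highest dose lines 7452.

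The fifth comparison asked whether the palbociclib change differed between the cell lines as labelled, by an interaction term. S100A6, a calcium-binding protein (chromosome 1, 153534599 to 153536244), rose in MCF7 (6.09) and fell in the libraries labelled T47D (-4.71), a difference of 10.80 ± 0.68 (adjusted p = 9.34e-15). HENMT1, an RNA methyltransferase (chromosome 1, 108648290 to 108661526), went the other way (-2.86 and 9.62, a difference of -12.44 ± 0.61, adjusted p = 2.23e-17). CDK6 fell in MCF7 (-2.75) and rose in T47D-labelled lines (1.08; difference -3.83 ± 0.56, adjusted p = 1.64e-06). CDKN2A was near 0 in MCF7 parental cells and higher in the MCF7 palbociclib lines (4.19). Whether MCF7 cells account for this stays open, as in the first comparison. CDKN2A fell in T47D-labelled lines (difference 9.12 ± 0.70, adjusted p = 6.85e-12). On a scaling of all 42 libraries its levels were near each other in the palbociclib lines (1.358 and 1.28 CPM) and apart in the parental cells (0.0659 and 38.84 CPM). E2F1 (1.17 and -1.05; difference 2.21 ± 0.49) and GREB1 (-2.50 and -6.47; difference 3.96 ± 0.52) also differed. ESR1 (0.38 ± 0.47, adjusted p = 0.639), EGFR (-0.12 ± 0.49, adjusted p = 0.961) and CCNE1 (-0.51 ± 0.38, adjusted p = 0.368) were not called as different.

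Of the lists, 5 were called in the interaction and all 5 calls were lost with an estimated correlation (adjusted p 0.205 to 0.789). The MCF7 change was above that of the T47D-labelled lines in 18 of 50 DNA replication genes and below it in 0 (0.000702), in 21 and 9 of 46 oestrogen response genes (0.000702) and in 17 and 0 of 39 glycolysis and hypoxia genes (1.35e-05). It was below in 18 and above in 6 of 42 NF-kB and cytokine genes (0.00673) and in 13 and 3 of 34 p53 targets (0.0155, lost in the highest dose lines at 0.52). Examples were IGF1R (4.34), PFKFB3 (4.12) and PPM1D (-3.21), of which PPM1D lies in the chromosome 17 block described below. The other 26 lists were not called. Without set 1 the MCF7 change was above for G2/M (0.000963) and below for the unfolded protein and ATF4 (0.0103), fatty acid (0.0294), endothelial (0.0367) and ribosomal lists (0.0397), each then called. Called without replicate 1 were these 5 lists and the immediate early genes (0.0305), and with the covariate G2/M, fatty acid and endothelial genes (0.0318, 0.0488 and 0.0498), so that 4 to 11 lists were called over these alternatives and the highest dose lines. Median, mean and test differed in sign for the mesenchymal, cholesterol synthesis, ABC transporter, growth factor receptor and leukocyte lists.

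edgeR called 5142 of 20243 genes in the interaction, 2523 higher and 2619 lower, and 2944 without the libraries of replicate 2. Of 2116 called in it and in both cell lines, 1100 had the same direction and 1016 opposite directions.

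The arms were also compared by their called genes. Between the MCF7 and the T47D-labelled palbociclib lines, which share no controls, 2254 genes were higher in both and 2204 lower in both, where independent arms would give 1198.2 and 1205.9, and 1024 went in opposite directions against 2404.4. The change correlated across 16591 genes (Pearson r = 0.595, Spearman rho = 0.46). Between the MCF7 palbociclib and abemaciclib lines, which share their controls, 1329 were higher in both, 1737 lower in both and 1132 opposite, against 739.3, 1575.5 and 2200.9 for independent arms (r = 0.163, rho = 0.232). Unchanged simulated groups with shared controls gave 0 calls in the same direction, a mean r of 0.601 and a covariance of 0.179, against 0.638 observed, a difference of 0.459. With no changed gene, a mean of 0.1 genes was called there in the palbociclib arm, so the 0 was fixed in advance. It does not tell how many shared calls the shared controls give where many genes are called. With the controls split between the arms, 600 were higher in both, 723 lower in both and 473 opposite, against 307.3, 702.6 and 954.2, and r was 0.137.

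Each dose line was set against its parental cells. The MCF7 palbociclib lines gave 5539, 5083, 5750 and 5373 called genes from 1.2 to 4.8 µM, the abemaciclib lines 6086, 5875 and 5998 from 0.5 to 1.5 µM, and the T47D-labelled lines 10869, 10920, 10917 and 10981. The abemaciclib counts fell to 896, 742 and 1122 with arm-matched parental replicates. Single libraries also moved them: without 1 library of its own line the count was 1097 (replicate 3) or 2181 (replicate 2) at 0.5 µM, 457 (replicate 3) or 1533 (replicate 1) at 1.0 µM, and 862 (replicate 1) or 2291 (replicate 3) at 1.5 µM.

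Genes named along the palbociclib dose were chosen among called genes whose group means were ordered by dose, so a change at each step follows from that choice. Each dose is 1 line, so dose and line cannot be separated. For the MCF7 trend as a whole chance was not excluded. In MCF7, PXDN, a matrix peroxidase (chromosome 2, 1631887 to 1744852), fell from 265 to 90.7, 2.06 and 0.306 CPM from 1.2 to 4.8 µM (-2.91 ± 0.23 per µM, adjusted p = 1.15e-08), and the proteoglycan gene BGN from 60.4 to 6.56, 1.85 and 0.406 CPM (-1.95 per µM, adjusted p = 4.8e-05). SERPINB5, a serpin of epithelial cells, rose from 0 to 0.858, 7.62 and 13.3 CPM (3.02 ± 0.44 per µM, adjusted p = 0.000103). MX2, an antiviral GTPase (chromosome 21, 41361943 to 41409390), rose from 0.0207 to 1.38, 6.12 and 12.6 CPM (2.39 ± 0.49 per µM, adjusted p = 0.00212). In the T47D-labelled lines MX2 rose from 0.488 to 0.818, 4.78 and 65.3 CPM (1.99 ± 0.16 per µM, adjusted p = 6.63e-07), against 2.23 CPM in T47D parental cells, and OAS1, which senses double-stranded RNA, from 0.302 to 0.583, 1.65 and 36.0 CPM (1.85 ± 0.19, adjusted p = 4.76e-06), against 4.24. EPGN and OAS2 rose there too, and SLC16A5, ANPEP and the protease gene KLK6 fell (KLK6 -1.21, adjusted p = 2.81e-06). The call of FOS (-1.44 ± 0.48, adjusted p = 0.0494) was lost under 4 of 10 alternatives and without any 1 of 9 libraries.

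**Figure D4:**
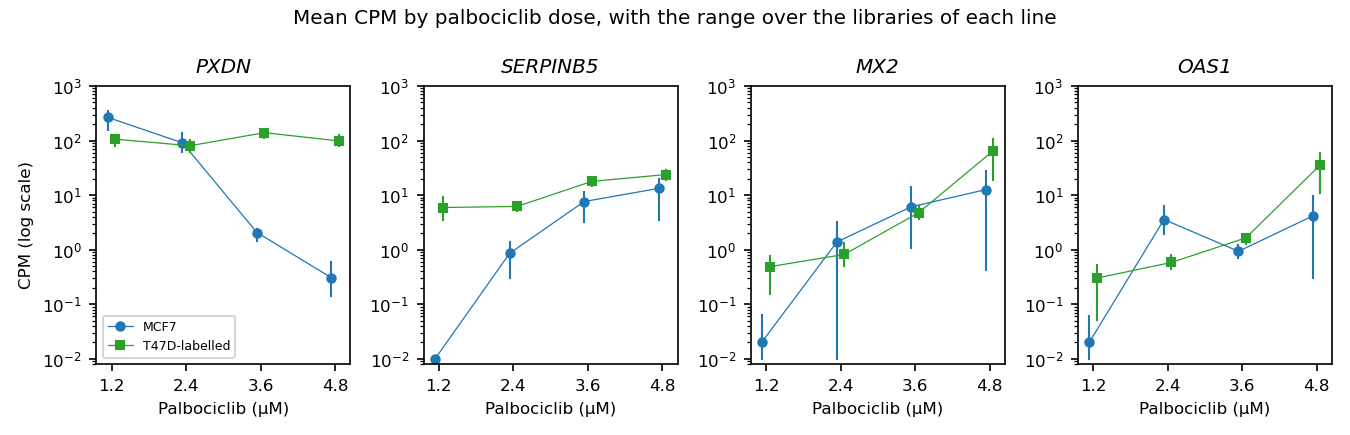
Mean CPM on a log axis against the palbociclib dose in µM for 4 genes, with bars for the range over the 3 libraries of a line and values under 0.01 drawn at 0.01. PXDN fell from 265 to 0.306 CPM in MCF7, and MX2 rose to 12.6 CPM in MCF7 and 65.3 CPM in the T47D-labelled lines at 4.8 µM.

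edgeR called 1820 of 18059 genes along the dose in MCF7 (641 up, 1179 down) and 2861 of 18245 in the T47D-labelled lines (1256 up, 1605 down), of which 400 and 149 also changed by at least 2-fold per µM. The MCF7 count was 965, 973 and 2957 without replicate 1, 2 or 3 of the 1.2 µM line and 926 and 930 without replicate 2 or 3 of the 4.8 µM line. Other assignments of the 12 MCF7 libraries to the doses called up to 5836 genes. The T47D-labelled count was 1895 without replicate 3 of the 1.2 µM line and 1862 without replicate 2 of the 4.8 µM line. Along the abemaciclib dose edgeR called 0 genes, with 740 at an unadjusted p under 0.05, and DESeq2 called 2. As a check, MCF7 parental replicates 1 to 3 were set against 4 to 6, and edgeR called 0 of 15319 genes, with 344 at an unadjusted p under 0.05, while DESeq2 called 1.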

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

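Tests chosen only after their results were seen were those of swapped labels, of an MCF7 origin, of library quality as the whole cause of the abemaciclib calls, and every fit with a covariate.

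Of 45 named genes or measures checked in the 6 MCF7 parental libraries, 10 had 1 library far from the other 5, where chance gives about 1 in 20. Replicate 1 stood apart in CCNE1 (3.939 CPM, the others 11.6 to 14.5), CLEC3A (35.84, the others 13.9 to 21.7), CYP4Z1 (223.7, the others 34.4 to 84.6) and IGFBP5 (205.3, the others 27.3 to 85.8). Replicate 2 stood apart in GRHL2 (168 CPM, the others 91.4 to 119.5) and MKI67 (772.6, the others 34.6 to 276.1). Replicate 4 stood apart in BCL2 (4.84 CPM, the others 11.2 to 12.2), CDK4 (159.4, the others 58.8 to 83.4), FGFR1 (32.05, the others 20.04 to 24.1) and ISG15 (12.69, the others 2.97 to 5.03). The 10 genes fall in 3 of the 6 libraries.

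The change from parental to palbociclib-resistant lines differed between the cell lines as labelled in 5142 genes by the interaction term. Among the preset genes these were CDK6 (-3.827), CDK2 (1.231), E2F1 (2.205), CDKN1B (-1.613), CDKN2A (9.123), GREB1 (3.956), TFF1 (-5.527), BCL2 (-2.936), STAT3 (1.03) and ABCG2 (-3.271). The call of BCL2 was lost in the highest dose lines and without replicate 1, 2 or 3, that of STAT3 without replicate 1, that of CDK2 without replicate 3 and that of TFF1 without replicate 1. Among genes that went in opposite directions the largest differences were S100A6 (10.798), CXCL12 (9.457), TENM3 (9.119), COL12A1 (8.776), TENM2 (8.47), NRCAM (-10.783), NUP210L (-11.823), VWDE (-11.998), MAOB (-12.411) and HENMT1 (-12.438). TENM3 stood at 21.54 and 28.71 CPM in the MCF7 and T47D-labelled palbociclib lines and at 0.3287 and 251.1 CPM in their parental cells, and CDKN2A at 1.358 and 1.28 against 0.0659 and 38.84 CPM. Gene lists that differed, each losing its call with an estimated correlation, had median differences of 0.791 for DNA replication, 1.596 for oestrogen response, 1.221 for glycolysis and hypoxia, -2.137 for NF-kB and cytokines and -0.987 for p53 targets.

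Some reads were counted to no gene, in counters outside the comparisons. Reads matching more than 1 gene had a median of 12.73% of all reads in the abemaciclib lines and 10.3% in MCF7 parental cells, and 9.044% in the T47D-labelled lines against 8.80% in T47D parental cells. Reads aligned to more than 1 place had medians of 6.787% in the abemaciclib lines against 4.16%, and 5.618% in the T47D-labelled lines against 5.08%.

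The libraries labelled T47D palbociclib-resistant resembled the MCF7 palbociclib lines (rho 0.907 to 0.935 across genes, with genes not independent) and stood nearer MCF7 than T47D parental cells, where swapped labels are argued against, since 0 of 4 MCF7 palbociclib line means stood nearer T47D parental cells. A preset test asked whether the arms differ by chromosome region as their parental lines do: r over 325 windows of 30 genes was 0.458, between its bounds of 0.3 and 0.5, so that cells of 1 other line in both arms and a shared change of state cannot be told apart by it. A second test, added after that value, removed GC content and length and gave 0.207 (0.888 for the abemaciclib arm against MCF7 parental cells), which argues against each arm keeping the regional pattern of its own line. In a block on chromosome 17 (58192737 to 62065282), 93.33% of the genes at least 4-fold higher in MCF7 than in T47D parental cells (14 of 15) stood nearer MCF7 in the T47D-labelled lines, against 52.4% of 571 such genes elsewhere, so cells of MCF7 origin may be present there, though neighbouring genes are not independent and 1 block is 1 observation. In the MCF7 palbociclib lines 12 of these 15 genes and 346 of the 571 elsewhere stood nearer MCF7. At 9p21 the genes went both ways, so an MCF7 origin stays open: MTAP (0.418 CPM, 25.8 in T47D and 0.068 in MCF7 parental cells) and HACD4 (0.83, 12.3 and 0.101) stood near MCF7, CDKN2B (6.74, 7.72 and 0.00796) near T47D, and IFNE (1.89) was at 0 in both. In the MCF7 palbociclib lines CDKN2A (1.36 CPM) and CDKN2B (2.16) stood above MCF7 parental cells (0.0659 and 0.00796). MTAP (0.286 and 0.068) and HACD4 (0.115 and 0.101) were low in both. Whether MCF7 cells account for this stays open.

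More genes were called than not in the abemaciclib lines, whose libraries had few reads outside genes. With the share of those reads as a covariate, 3242 of the called genes were still called. This argues against a linear effect of the share, as seen within groups, as the whole cause. The share had medians of 2.25% in this arm and 7.44% in parental cells. Arm and share are thus hard to separate, and the covariate cannot exclude library quality as the whole cause. Quality may be a part of it: across genes, the deviation of parental replicate 4, the parental library with the lowest share, had r = 0.741 with the abemaciclib change, or 0.563 with no shared library, while the other 5 parental libraries gave -0.408 to 0.338. That test rests on 1 library and on genes, which are not independent. A biological difference between the lines stays open beside it.

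Interferon genes were higher in the abemaciclib lines, where a technical origin was weighed. Their median log2 change was 2.33 with the covariate and 2.17 without it, and 27 of the 29 called members were still called. This argues against an effect of the share as seen within groups. Arm and share go together too closely for the covariate to exclude library quality. Between parental replicates 4 to 6 and 1 to 3 the median difference over 38 members was -0.012, which argues against a difference between the sets of libraries. In parental replicate 4, the parental library with the lowest share, ISG15 stood at 12.69 CPM, against 2.97 to 5.03 in the other parental libraries. A response in the cells may stand behind the higher interferon genes, as a hypothesis from the data that it was tested on. A part played by library quality stays open beside it, and the list's call was lost with an estimated correlation.

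Other splits of the same libraries were drawn for each count of genes, 100 where more exist. They move single libraries between groups, so they cannot tell an effect of a drug from other differences between lines or cultures. For the T47D-labelled lines the highest other count came near the real one, so the size of that count tells little. The real split gave the highest count, a share under 0.05, for the MCF7 palbociclib lines (7942, the highest other 4020), the abemaciclib lines (10268 and 5567), the T47D-labelled lines (12209 and 11767), palbociclib against abemaciclib (11980 and 9417) and the interaction (5142 and 4207). The same held for the MCF7 palbociclib lines from 1.2 to 4.8 µM (5539 and 3202, 5083 and 1853, 5750 and 1, 5373 and 15) and the abemaciclib lines from 0.5 to 1.5 µM (6086 and 1, 5875 and 2360, 5998 and 2807), each over 84 splits, and for the T47D-labelled trend (2861 and 143). For the MCF7 palbociclib trend chance was not excluded: 5 of 100 splits gave as many as its 1820 genes, the highest 5836, which points to a structure of these libraries, left open here. For the abemaciclib trend, with 0 calls in edgeR (740 at an unadjusted p under 0.05 and 2 in DESeq2), all 100 splits gave as many, the highest 2. The 4 T47D-labelled dose lines (10869, 10920, 10917 and 10981, the highest other 0 in each) and the parental check (0 in edgeR with 344 at an unadjusted p under 0.05, 1 in DESeq2, and 0 in all 10 splits) have too few splits for a share under 0.05.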

How the results depend on the processing

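The covariate (share of reads outside genes), the fits without the 4 palbociclib libraries of set 1 and the gene lists along the dose were chosen after seeing the data, the other alternatives before. Up to 13 alternatives were tried per result, beside each library left out in turn. Without the leave-outs, 220 counts of genes or lists stayed within 1.5 times their value and 37 did not. Named genes kept direction and call in 5654 values, lost the call in 187, gained one in 36 and reversed in 3. RLE factors ended 3 of these calls and upper-quartile factors 3, arm-matched parental replicates 38, a 2-fold minimum 35 (by its construction, for changes under 2-fold) and the covariate 22. Where no cause is given below, the cause was not tested.

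With only the parental replicates matched to an arm by library name (3 control libraries in place of 6), the abemaciclib count was 6183, of which 6130 were called with all 6. The counts at 0.5, 1.0 and 1.5 µM were 896, 742 and 1122, the 1.0 µM line then having 421 higher and 321 lower. Palbociclib against abemaciclib gave 3992 in this way and 7452 in the highest dose lines. With the covariate the abemaciclib count was 3561, and 1308, 1344 and 1648 by dose, while the MCF7 palbociclib trend gave 4800 (2388 up and 2412 down, 1818 of them called without it). With a 2-fold minimum the MCF7 palbociclib trend gave 400, the T47D-labelled trend 149 and the T47D-labelled comparison 7713. Under that minimum the MCF7 arms had 670 genes higher in both and 693 opposite, and the palbociclib arms 1423 and 474. Split controls gave the MCF7 arms 600 higher in both, 723 lower in both and 473 opposite. The abemaciclib trend had 0 calls in edgeR, 5 with no count filter and 2 with DESeq2, and the comparison of parental replicates had 1 with DESeq2.

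With an estimated correlation 6, 0, 2, 3 and 0 gene lists were called in the MCF7 palbociclib, abemaciclib, T47D-labelled, between-drug and interaction comparisons, against 14, 9, 14, 13 and 5 with the preset one. The fry test, which does not compare a list with other genes, called 20, 17, 23, 21 and 16. The interaction called 10 lists without set 1 and 8 with the covariate, among them endothelial markers (adjusted p = 0.0367 and 0.0498), fatty acid synthesis (0.0294 and 0.0488) and G2/M (0.000963 and 0.0318) in both, and ribosomal (0.0397) and unfolded protein genes (0.0103) without set 1. The covariate also called immediate early genes in the T47D-labelled lines (0.0487).

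Between the drugs CCND1 reversed to -0.326 in the highest dose lines (adjusted p = 0.451, with 0.0133 to 1 over its alternatives), and with the covariate CCNE2 reversed to -0.065 and STARD4 to -0.134. The basal list in the abemaciclib lines, with a median of -0.271 on the log2 CPM of the list tests, and the growth factor receptors in the T47D-labelled lines, with -0.372 (edgeR medians -0.261 and -0.447), pointed up and down respectively in camera without a call, while fry called them the other way.

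Without 1 library each, the abemaciclib counts ranged from 1097 to 7121 at 0.5 µM, from 457 to 6814 at 1.0 µM and from 862 to 6844 at 1.5 µM, each highest without parental replicate 4. The MCF7 palbociclib trend ranged from 926 to 2957, the T47D-labelled trend from 1862 to 3205, and the interaction from 2944 (without replicate 2) to 5340. The interaction's lists ranged from 5 to 11, the highest without replicate 1. The other counts of genes moved by less than 1.5 times, with 7092 to 8950 for the MCF7 palbociclib lines, 9120 to 10738 for the abemaciclib lines, 11292 to 12777 for the T47D-labelled lines and 11429 to 12523 between the drugs. The call of CCND1 was lost without MCF7 parental replicate 3 or 4 in the MCF7 palbociclib lines and without T47D parental replicate 1 in the T47D-labelled lines, where that of CDH5 was lost without replicate 1 of the 4.8 µM line. Among lists near the threshold in the abemaciclib lines, homologous recombination was called without parental replicate 1 (adjusted p = 0.0115) or replicate 1 of the 1.2 or 4.8 µM palbociclib line, unfolded protein and ATF4 without parental replicate 2 (0.0114) or 3 or replicate 3 of the 1.0 µM line, and cholesterol synthesis without parental replicate 2 (0.0292). In the MCF7 palbociclib lines cholesterol synthesis was called without parental replicate 1 (0.0197), and the MHC class I call was lost without parental replicate 2 (0.0529). The between-drug call of the basal list was lost without replicate 1 of the 1.2 or 2.4 µM or replicate 2 of the 4.8 µM palbociclib line. Immediate early genes were called in the T47D-labelled lines without parental replicate 1 (0.0356). They were also called without replicate 1 (0.0478) or 3 (0.0463) of the 1.2 µM line or replicate 3 of the 3.6 µM line (0.0455). Leaving out single libraries ended 148 calls of named genes and gave 14.

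Neither title nor set numbers met the condition for pairs, that the deviations from the group means correlate over 0.1 in every pair. As a hint from the data, the best match of a library had the same title number for 16 of 27 MCF7 and 10 of 15 T47D libraries, and the same set number for 17 of 27 and 10 of 15. Set numbers tied some MCF7 libraries: in set 6 all 10 pairs were over 0.1 (median r 0.499, lowest 0.317) and in set 1 6 of 10 were (median r 0.667, lowest -0.184), with medians of 0.025 to 0.164 in the other sets. As blocks, title and set numbers gave 6204 and 7923 genes for the MCF7 palbociclib lines, 8517 and 8820 for the abemaciclib lines, 11350 and 5397 between the drugs, 4445 and 5882 in the interaction, and 1848 and 3040 for the MCF7 palbociclib trend. Blocks by set number ended 27 calls of named genes and gave 3. With these blocks, lists called beyond those above were G2/M (0.00399), homologous recombination (0.00106) and unfolded protein and ATF4 (0.00106), all down, in the abemaciclib lines. Between the drugs they were G2/M (3.33e-05), DNA replication (0.00256), homologous recombination (0.0126), unfolded protein and ATF4 (0.0154) and NF-kB (0.0487), all up, and the ribosomal call ended (0.11). Also called with these blocks were G2/M in the interaction (0.00731), oxidative phosphorylation in the MCF7 palbociclib lines (0.0335), where the histone call ended (0.106), and immediate early genes in the T47D-labelled lines (0.0397).

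Depth limits what 0 counts show, since 3 counts over a group could pass unseen. In simulated data 65.5% of 4-fold but 7.0% of 2-fold changes were called in the MCF7 palbociclib comparison. Far fewer genes changed there than were called in the data, so these shares need not describe the data. Still, an uncalled gene of small change is not shown to be unchanged.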

Other observations

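Gene lists along the dose were tested only after the trends of single genes had been seen. In the T47D-labelled lines, 39 of 52 type I interferon genes rose with the palbociclib dose and 1 fell (median 0.50 per µM, adjusted p = 1.7e-22, lost at 0.29 with an estimated correlation), while the comparison with parental cells did not call that list. Among its members OAS2 went from 1.58 CPM at 3.6 µM to 19.3 CPM at 4.8 µM, against 18.3 CPM in T47D parental cells, and OAS1 from 1.65 to 36.0 CPM. At 4.8 µM alone the interferon list was called against parental cells (up, adjusted p = 4.44e-06). IFIT2, an interferon-induced protein, stood at 13, 12.6, 7.27 and 58.3 CPM from 1.2 to 4.8 µM. The other 11 calls were lost in the same way (0.233 to 0.909). MHC class I genes rose in 9 of 21 members and fell in 0 (adjusted p = 6.79e-05), unfolded protein and ATF4 genes fell in 17 of 40 and rose in 1 (7.09e-06), and p53 targets fell in 14 of 34 and rose in 1 (0.000209). Lists called upward were mesenchymal (18 rose and 7 fell of 55, 0.000362), NF-kB (13 and 4 of 41, 0.0013), G2/M (4 and 0 of 50, 0.000587) and fibroblast genes (4 and 0 of 6, 0.00371). Lists called downward were luminal (2 rose and 12 fell of 30, 0.0031), ribosomal (0 and 14 of 78, 0.000424), ABC transporter (0 and 5 of 16, 0.0392) and endothelial genes (0 and 1 of 4, 0.0468).

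In MCF7, 14 of 49 interferon genes rose with the palbociclib dose and 5 fell (median 0.36 per µM, adjusted p = 0.0085, lost at 0.716 with an estimated correlation), with IFIT2 at 0.0869, 5.85, 6.17 and 18.5 CPM against 0.27 CPM in parental cells. The other 7 calls were lost in the same way (0.28 to 0.743), and chance was not excluded for this trend as a whole. Ribosomal protein genes fell in 29 of 78 members and rose in 0 (2.26e-16) and mitochondrially encoded genes in 9 of 13 and 0 (3.44e-07). Mitochondrially encoded genes took 6.93, 25.27 and 14.38% of counts in replicates 1, 2 and 3 of the 1.2 µM line. The other MCF7 palbociclib libraries lay between 3.897 and 12.03%, and the lists along the dose were not tested without single libraries. Lists called upward were p53 (6 rose and 0 fell of 34, 0.00421), NF-kB (8 and 2 of 37, 0.00228), mesenchymal (12 and 3 of 54, 0.00787) and DNA replication genes (7 and 1 of 50, 0.00265). Oxidative phosphorylation was called downward (1 rose and 10 fell of 77, 0.0209). Along the abemaciclib dose the interferon list was called downward (-0.30 per µM, adjusted p = 0.00122, 0.969 estimated), with 0 of 49 members called in edgeR. The count of MCF7 trend genes moved from 1820 to 4800 with the covariate. In both cell lines each dose is 1 line, so the dose and the line cannot be separated.

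Genes that separate the parental lines were followed in the resistant ones. Of 57 genes above 20 CPM in MCF7 parental cells and called at least 64-fold lower in T47D parental cells, 55 stood above 5 CPM in the abemaciclib lines, 33 in the MCF7 palbociclib lines and 31 in the T47D-labelled lines. Of 77 genes with the opposite pattern, 2, 13 and 15 did. The MCF7 palbociclib line means had a rho of 0.852 to 0.861 with MCF7 parental cells and 0.788 to 0.802 with T47D parental cells, the abemaciclib ones 0.93 to 0.935 and 0.795 to 0.8, and the parental lines 0.868 with each other. The endothelial markers that rose from 0 in the T47D-labelled lines were partly present in MCF7 parental cells, with EMCN at 2.91 and CDH5 at 4.03 CPM there, against 5.50 and 2.32 CPM in the T47D-labelled lines. These 4 values were scaled by library total alone, without TMM factors. On a scaling of all 42 libraries CDKN2B, a neighbour of CDKN2A on chromosome 9, stood at 7.72 CPM in T47D parental cells, 6.74 in the T47D-labelled lines and 2.16 in the MCF7 palbociclib lines.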
